A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

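RNA from roots or galls of Oryza sativa cv. Nipponbare was sequenced as 3′ mRNA libraries (QuantSeq FWD, NextSeq500), with 12 libraries in 4 groups of 3. The labels describe the 3 libraries of a group as independent biological replicates, each a pool of 4 to 5 plants. AO stands for ascorbate oxidase, sprayed on leaves at 20 U/mL with 0.02% Tween20; plants without AO received the carrier alone. Infected plants were given 250 to 300 juveniles of Meloidogyne graminicola at 24 h after the spray, and tissue was taken 3 days later.

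The authors deposited, for each library, a file of raw counts per gene and a file of signal. The values show that the signal is the raw count divided by 1 size factor per library, so the raw counts were used here. The submitters' notes name Trimmomatic 0.36, STAR 2.5.2a, SAMtools 1.3, DESeq2 2.1.20 and the genome build IRGSP-1.0; the counting tool and the annotation release are not given in the sources used here. Each file lists 35833 gene IDs, of which 35667 have the form of a rice locus and 166 do not; those 166 have 0 counts in every library. In all, 5345 IDs have 0 counts in all 12 libraries. Totals were 10665203 to 15107485 counts per library. A count of 0 allows up to 0.199 to 0.281 CPM (a count scaled to the size of its library) in a library, with 3 counts as the floor; such floors cover counting error only.

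Groups came from the sample titles. Genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3), which kept 19468, scaled by TMM factors and fitted with edgeR's robust quasi-likelihood model with 4 group means over all 12 libraries. There were 5 comparisons: AO against control in roots, AO against no AO in galls, gall against root without AO, gall against root with AO, and the interaction. P values were adjusted over all tested genes of each comparison by the method of Benjamini and Hochberg, with a threshold of 0.05. Errors of log2 fold changes are standard errors worked back from the fold change and the F statistic of the same model. They are unstable for very small changes. CPM are given as mean and SD over 3 libraries. Overlaps of gene calls were tested by a two-sided Fisher's exact test on the tested genes. Genes are correlated, so its p values overstate the evidence, and the expected counts and shares are the more useful figures. Principal components used log2 CPM with a prior count of 2. Gene lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a family.

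Gene names need care. The reference table used here matched 1 of the 35833 IDs and holds no descriptions, so IDs are printed as the files give them, and a gene's family is that under which the list holds it. List membership was written from general knowledge of rice, as IDs, not from an annotation. Of 31 lists planned before the data were examined, 20 needed descriptions and could not be formed. Lists planned as description patterns together with IDs were formed from the IDs alone, and so hold less than was planned. The phenylpropanoid and lignin list holds only phenylalanine ammonia-lyase genes, and the list of ethylene-responsive factors only 2 genes. The other 11 were jasmonate biosynthesis, jasmonate signalling, ethylene biosynthesis and signalling, ethylene-responsive transcription factors, salicylate pathway, phenylpropanoid and lignin biosynthesis, diterpenoid phytoalexin biosynthesis, pathogenesis-related proteins, ascorbate biosynthesis with oxidation and recycling, secondary cell wall and xylem, and root hair; 9 had at least 3 tested members. A further 8 lists were written after the files were read: green tissue, WRKY transcription factors, aquaporins, cell cycle and DNA replication, iron acquisition, nitrate with ammonium and phosphate transport, sugar transport and cleavage, and class III peroxidases. The WRKY and peroxidase lists had been planned as description patterns, and their IDs were written only then. As a check, recalled symbols were looked up in the reference table. Of 126 IDs whose symbol stood there once and on the ID's own chromosome, 123 followed the same order along the chromosome as in the table. The 3 out of order were Os08g0508800, Os03g0180900 and Os12g0178100. Symbols of 8 further IDs stood on another chromosome: Os10g0467800 and Os09g0422500 of the secondary wall list, Os02g0569900 of the diterpenoid list, Os01g0952800 and Os11g0134900 of the iron list, Os01g0600900 (green tissue), Os05g0583000 (WRKY) and Os02g0106100 (sugar). A further 35 were not in the table and 65 IDs had no symbol to look up. Reads shared between close relatives in a family were not examined here.

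The rule for naming genes was also set before the data were examined. In each comparison it takes the 5 largest rises and 5 largest falls among called genes that have a name in a list, a mean of at least 10 counts and groups that do not overlap, up to 4 members of each list by p, and the 4 loci of the insertion mutants that the labels list. Unlisted IDs, at most 2 per direction, were chosen by size of change.

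The alternatives were relative log expression size factors, the authors' size factors, no count filter, a stricter filter of 10 CPM in at least 3 libraries, DESeq2 1.42.0, a replicate block, only the compared groups in the fit, a required log2 change of 1, an estimated correlation between genes, and leaving out each library in turn. Called members of the later lists were run under the same alternatives. Leaving out control replicate 1 was added after its distance from the other control libraries was seen, for the comparisons that do not contain it and for counts adjusted over a list alone. A group left with 2 libraries was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

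The method was tested on simulated data in which 100 genes per size of change were altered among 19468. The altered genes were drawn only from those at or above a set mean CPM, so recovery at low counts was not tested. The ascorbate list was shifted as well, and its calls were not counted as false. Each gene had the same spread in all libraries, so no library stood apart as control replicate 1 did. For AO against control in roots the method recovered 81% of 2-fold and 99% of 4-fold changes with 4.1% false calls. For gall against root with AO it recovered 83% and 97% with 7.0% false calls, and for the interaction 55% and 98% with 10.0% false calls.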

Results

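Gene expression was measured in roots of the rice cultivar Nipponbare by 3′ end sequencing, in which each read comes from the end of a polyadenylated transcript. Plants 2 weeks old were sprayed on the leaves with ascorbate oxidase (AO), an enzyme that oxidises ascorbate, at 20 U/mL, or with the carrier alone. At 24 h after spraying, part of the plants received 250 to 300 juveniles each of the root-knot nematode Meloidogyne graminicola, which makes the root swell into galls. Samples were taken 3 days after inoculation, which is 4 days after AO. There were 4 groups of 3 libraries: control roots, AO-treated roots, galls, and galls of AO-treated plants, and each library was a pool of 4 to 5 plants. Infected plants were sampled as galls and uninfected plants as roots, so infection and tissue changed together, and any difference between gall and root holds both.

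Library totals ranged from 10665203 to 15107485 counts, and 19468 genes had enough counts to be tested. The first principal component held 33.2% of the variance and parted the 6 gall libraries from the 6 root libraries. The second component held 19.4% and placed control replicate 1 apart from the other control libraries. In that library 1968 genes lay over 1 log2 unit from the mean of the other 2 control libraries, against 252 to 1103 genes in each of the other 11 libraries compared in the same way. The jasmonate signalling list, written before the data were examined, had a median 0.58 log2 units above those 2 libraries, with 12 of its 16 tested members higher. The most abundant transcript, of Os11g0704500, took 9.51% to 14.08% of all counts. Its share was 9.51% in replicate 1 of the AO-treated galls, as low as in the untreated galls, and 12.89% and 12.94% in replicates 2 and 3, as high as in roots.

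**Figure D1:**
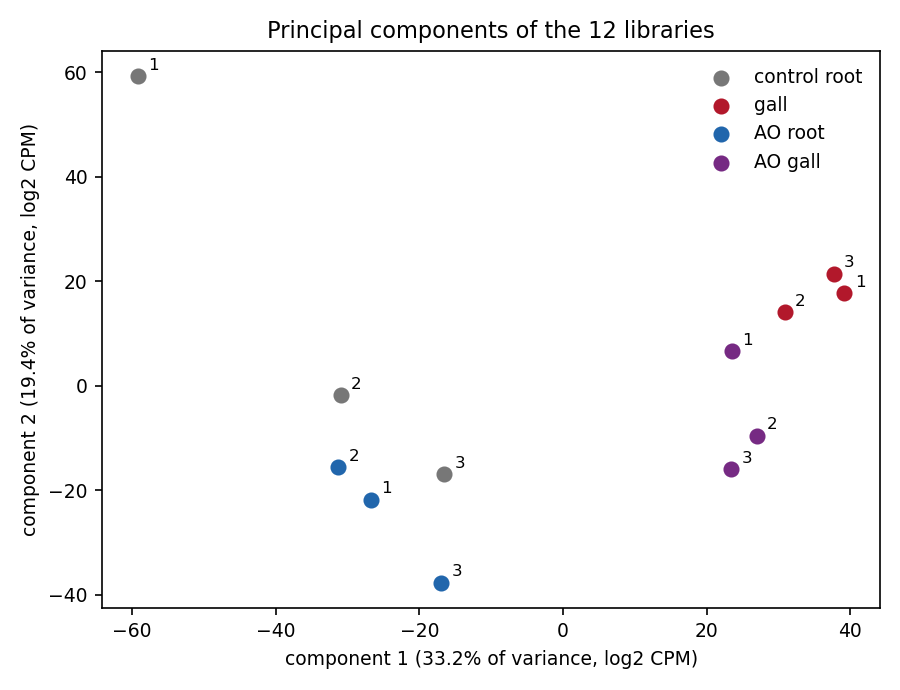
Scores of the 12 libraries on the first 2 principal components of log2 CPM (count scaled to the size of the library), with 33.2% and 19.4% of the variance, coloured by group and numbered by replicate. Gall libraries lie to the right of all root libraries, and control replicate 1 lies alone at the top with a score of 59.27 on the second component.

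The first question was how uninfected roots differed after the leaves had been sprayed with AO. A gene listed as an ethylene receptor, Os04g0169100, rose 2.32-fold (log2 1.21 ± 0.16 SE, n = 3 per group, adjusted p = 0.000371, edgeR), from 6.55 ± 0.80 to 15.2 ± 2.06 CPM (SD). A listed ethylene-responsive transcription factor, Os09g0287000, rose 2.21-fold (log2 1.15 ± 0.20, adjusted p = 0.00279). A gene listed as an ascorbate oxidase, a cell wall enzyme of the same kind as the sprayed one, had the largest fall among the listed genes that passed the test: Os06g0567200 went from 9.78 ± 1.39 to 2.90 ± 1.01 CPM (log2 −1.75 ± 0.31, adjusted p = 0.00539). The abundant ascorbate peroxidase gene Os07g0694700, listed as an enzyme that uses ascorbate to remove hydrogen peroxide, went from 852 ± 57.8 to 552 ± 30.7 CPM (log2 −0.62 ± 0.10, adjusted p = 0.00125).

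Few members of the listed pathways passed the test in AO-treated roots. Of 13 tested jasmonate biosynthesis genes and 16 jasmonate signalling genes, 0 passed over all genes tested, by edgeR or by DESeq2, while 4 and 5 had an unadjusted p under 0.05; adjusted over the list alone, 0 and 4 passed, the latter 2 higher and 2 lower, and 0 of either list without control replicate 1. The jasmonate signalling members with the smallest p were the MYB factor Os11g0684000 (log2 0.85, adjusted p = 0.103) and the JAZ repressor Os03g0402800 (log2 −0.77, adjusted p = 0.112). In the ethylene list 1 of 10 genes rose, the receptor named above, and 1 adjusted over the list alone. Of the ethylene-responsive factors 1 of 2 rose, and 2 adjusted over the list alone. In the ascorbate list 2 of 26 genes fell, the oxidase and the peroxidase above, and 3 adjusted over the list alone. Of 7 phenylpropanoid genes 1 fell, the phenylalanine ammonia-lyase gene Os02g0626600 (log2 −1.06 ± 0.24, adjusted p = 0.0197), an entry enzyme of lignin and phenolic synthesis, and 2 fell adjusted over the list alone (1 without control replicate 1). That call was lost without control replicate 1 (adjusted p = 0.0503), AO replicate 2 (0.107) or AO replicate 3 (0.0789) and with only these 2 groups in the fit (0.0715). Of 10 pathogenesis-related and 5 salicylate genes 0 passed by either tool or adjusted over the list alone, and 1 and 2 had an unadjusted p under 0.05. In the diterpenoid phytoalexin list edgeR called 0 of 7 and DESeq2 1, with 4 at an unadjusted p under 0.05 and 3 lower adjusted over the list alone (0 without control replicate 1). In the secondary wall list both called 0 of 3, with 2 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (3 without control replicate 1).

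Over all tested genes, 830 passed an adjusted p of 0.05 in AO-treated roots, 423 higher and 407 lower, and 241 of them changed at least 2-fold, 134 higher and 107 lower. The lower genes were the majority without control replicate 2 (296 higher, 317 lower) or control replicate 3 (449 and 572). The libraries of the 2 groups did not overlap for 4116 genes, 21.1% of those tested, where chance gives 10%. Leaving out any 1 of the 3 AO libraries lowered the count to between 399 genes (without AO replicate 3) and 487 (without AO replicate 2). With only these 2 groups in the fit, the count was 356. The camera test called 0 of 9 lists as shifted against the other genes; the smallest adjusted p was 0.0721, shared by the diterpenoid, phenylpropanoid and secondary wall lists. The number was 1 list without control replicate 1 and 2 lists without control replicate 2, all lower.

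The same spray was then compared in infected plants, as AO-treated galls against untreated galls. A gene listed as PR1, Os07g0129200, whose family marks defence responses, rose 2.40-fold, from 20.7 ± 2.08 to 49.7 ± 8.65 CPM (log2 1.26 ± 0.20, n = 3 per group, adjusted p = 0.0042, edgeR). This was a rise towards the level of roots, which had 64.4 to 102 CPM without AO and 52.9 to 79.6 CPM with AO. In roots its change with AO was log2 −0.26 ± 0.19 (adjusted p = 0.547, edgeR). A smaller share of gall tissue in the AO-treated galls would also bring such a rise and cannot be told apart here. The same holds for other genes that moved towards the level of roots, in this comparison and in the interaction. The ethylene-responsive factor Os09g0287000 rose 2.19-fold (log2 1.13 ± 0.19, adjusted p = 0.00498), from 3.07 ± 0.14 to 6.72 ± 1.61 CPM. Both kept their call in every alternative run.

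A listed lipoxygenase gene, Os03g0699700, of an enzyme family in which some members start jasmonate synthesis, rose 2.82-fold in galls after AO (log2 1.49 ± 0.34, adjusted p = 0.0316). Whether it takes part in that synthesis was not checked here. Its call was lost without gall replicate 2 (adjusted p = 0.121), gall replicate 3 (0.108) or AO-treated gall replicate 3 (0.144), and with a replicate block (0.0662). The ethylene receptor gene Os04g0169100 rose 1.55-fold (log2 0.64 ± 0.15, adjusted p = 0.039). That call was lost without gall replicates 1 (0.152), 2 (0.138) or 3 (0.0716) and without AO-treated gall replicates 1 (0.107) or 2 (0.145), and with a replicate block (0.0534). A listed JAZ repressor of jasmonate responses, Os07g0615200, fell from 84.8 ± 9.48 to 61.0 ± 0.914 CPM (log2 −0.48 ± 0.12, adjusted p = 0.047). Its call was lost without gall replicates 1 (0.179) or 3 (0.192) and without AO-treated gall replicates 1 (0.104), 2 (0.126) or 3 (0.163), and with a replicate block (0.0575).

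By list, 1 of 13 jasmonate biosynthesis genes rose in AO-treated galls, 1 of 16 jasmonate signalling genes fell, 1 of 10 ethylene genes rose, 1 of 2 ethylene-responsive factors rose and 1 of 10 pathogenesis-related genes rose. Adjusted over the list alone the numbers were 1, 1, 2, 1 and 1. Of 26 ascorbate genes edgeR called 0 and DESeq2 3, with 5 at an unadjusted p under 0.05 and 3 lower adjusted over the list alone; the ascorbate oxidase Os06g0567200 had a log2 difference of −1.01 ± 0.28 (adjusted p = 0.0844). In the salicylate, diterpenoid and secondary wall lists 0 members passed either way or by DESeq2, with 1, 0 and 0 at an unadjusted p under 0.05. In the phenylpropanoid list both tools called 0 of 7, with 1 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. As whole lists, camera called the ascorbate list lower (median log2 −0.15, 21 of 26 members lower, adjusted p = 0.0154), the jasmonate signalling list lower (median −0.42, 12 of 16 lower, adjusted p = 0.046) and the pathogenesis-related list higher (median 0.23, 7 of 10 higher, adjusted p = 0.046). With an estimated correlation between genes none of these held: the adjusted p was 0.175, 0.631 and 0.631. The ascorbate list was also lost without gall replicate 3 (adjusted p = 0.0506). The jasmonate signalling list was lost without gall replicates 1 (0.15) or 3 (0.142) or AO-treated gall replicates 2 (0.0594) or 3 (0.087), and under a stricter count filter (0.275). The pathogenesis-related list was lost without gall replicate 2 (0.47) or AO-treated gall replicates 1 (0.0693) or 3 (0.161), under a stricter count filter (0.214) and without a count filter (0.127). The number of lists called was 1 without gall replicate 3 or without AO-treated gall replicate 3.

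In all, 462 genes passed between AO-treated and untreated galls, 341 higher and 121 lower, and 93 of them changed at least 2-fold, 64 higher and 29 lower. Groups did not overlap for 4520 genes, 23.2% of those tested, where chance gives 10%. The count was 190, 290 and 210 without gall replicates 1, 2 and 3, and 235 and 176 without AO-treated gall replicates 2 and 3. It was 900 with only these 2 groups in the fit (547 higher, 353 lower), and 1124 when control replicate 1, which is in neither group, was left out of the shared estimate of spread (704 and 420). Higher genes were the majority in every alternative run, though the excess was smaller in these fits and under a stricter count filter (293 and 181).

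**Figure D2:**
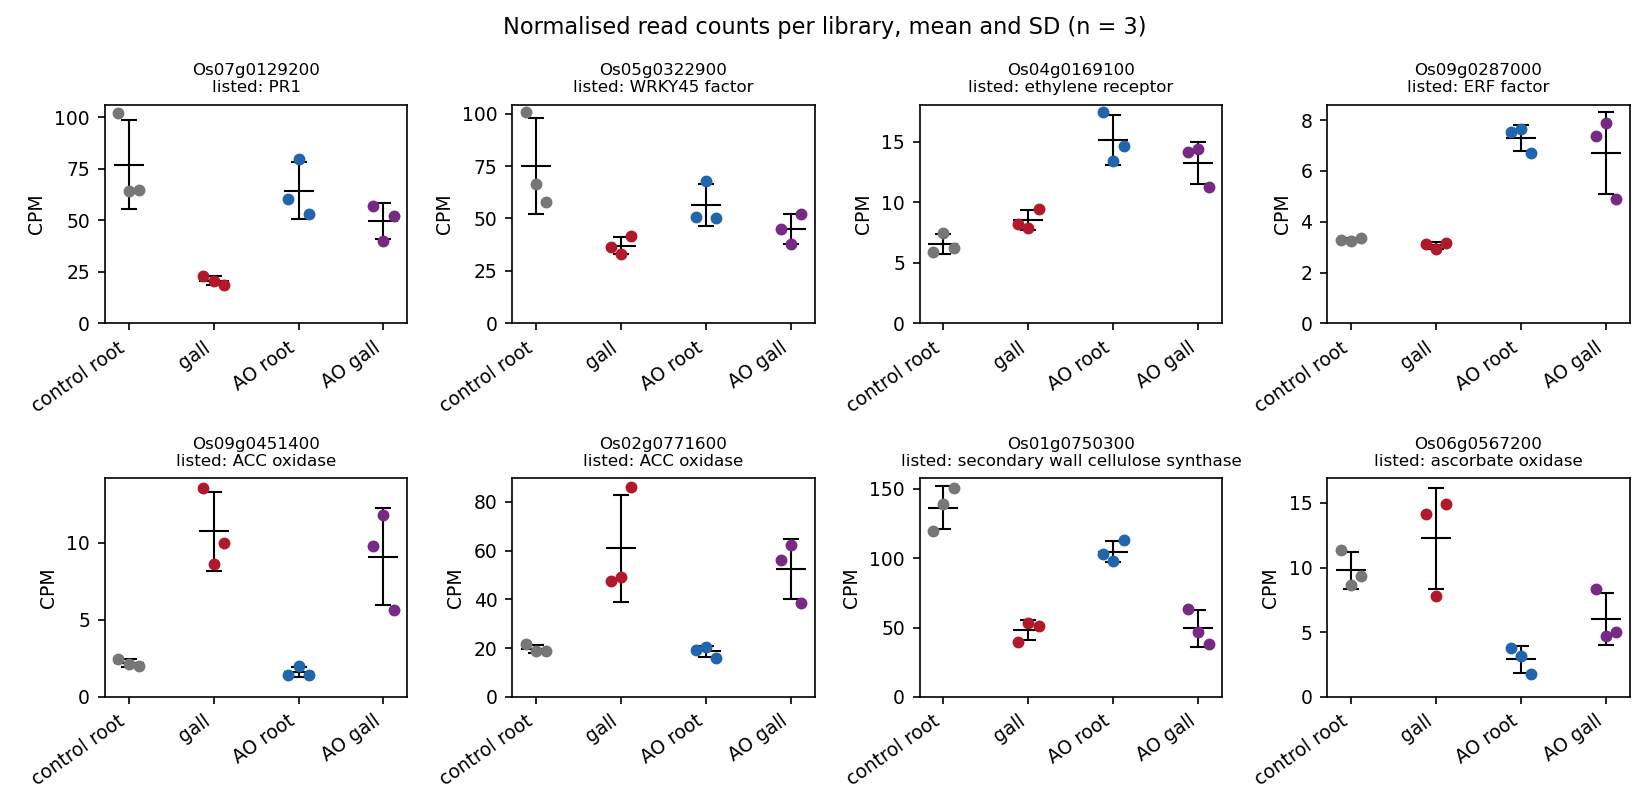
CPM of 8 listed genes in each of the 12 libraries (points), with the group mean and SD (bars, n = 3), on axes that start at 0. The PR1 gene Os07g0129200 averaged 77.0 CPM in control roots, 20.7 in galls and 49.7 in AO-treated galls.

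The response to AO was compared between tissues, using contrasts with no library in common. Of the genes called in roots and in galls, 174 were higher in both and 47 lower in both, where 7.41 and 2.53 were expected if the calls were independent (two-sided Fisher's exact test, p = 1.4e-207 and 1.83e-47). The ethylene-responsive factor Os09g0287000 and the ethylene receptor gene Os04g0169100 were among those higher in both. Only 3 genes were called in opposite directions. Of the 423 genes higher with AO in roots, 94.3% had a positive difference in galls, and of the 407 lower ones 87.0% had a negative difference. Across all tested genes, which are not independent replicates, Pearson's r was 0.34 and Spearman's rho 0.33. The overlap of 221 genes fell to 112 without gall replicate 1, to 120 without gall replicate 3, to 141 without AO replicate 3, and to 142 and 112 without AO-treated gall replicates 2 and 3. It was 413 without control replicate 1.

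Galls were next compared with uninfected roots in plants without AO. Genes of the ethylene list, which holds both synthesis and signalling, moved in both directions: of 10 tested members 4 rose and 2 fell. The risers were a receptor and 3 listed ACC oxidases, which make ethylene in the last step: Os09g0451400 by 4.85-fold (log2 2.28 ± 0.27, adjusted p = 5.5e-05, edgeR, n = 3 per group), Os09g0451000 by 3.44-fold (log2 1.78 ± 0.34, adjusted p = 0.00561) and Os02g0771600 by 3.09-fold (log2 1.63 ± 0.23, adjusted p = 0.000447). The listed ACC oxidase Os01g0580500 (log2 −1.70 ± 0.29, adjusted p = 0.00117) and the ACC synthase Os04g0578000 (log2 −1.70 ± 0.32, adjusted p = 0.00317) fell. The receptor, Os05g0155200, is named outside the rule, after its value was seen (log2 0.53 ± 0.14, adjusted p = 0.0212), and its call was lost without control replicate 2 (0.0637) or gall replicates 2 (0.0504) or 3 (0.106). Adjusted over the list alone 7 passed, 5 higher and 2 lower. The listed ascorbate oxidase Os06g0567900 rose 6.35-fold at a low level, from 0.205 ± 0.133 to 1.39 ± 0.496 CPM (log2 2.67 ± 0.49, adjusted p = 0.00182). Its control mean lay below the 0.225 to 0.281 CPM that a count of 0 allows in those libraries, so the size of the rise is uncertain. The log2 change was 3.26 without control replicate 1.

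All 3 listed cellulose synthases of the secondary wall, the thickened wall of xylem and fibre cells, fell in galls without AO. Os01g0750300 went from 136 ± 15.5 to 48.2 ± 7.37 CPM (log2 −1.50 ± 0.17, adjusted p = 3.79e-05), Os10g0467800 from 111 ± 16.4 to 43.9 ± 5.28 (log2 −1.34, adjusted p = 0.000147) and Os09g0422500 from 78.6 ± 11.8 to 32.0 ± 4.91 (log2 −1.30, adjusted p = 0.000154); all 3 also passed adjusted over the list alone. The symbols recalled for Os10g0467800 and Os09g0422500 stand on another chromosome in the reference table, so their place in this list is less sure than that of Os01g0750300. Camera called this list lower (adjusted p = 4.58e-09), and with an estimated correlation the adjusted p was 0.052.

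Defence lists were mixed in galls without AO. The PR1 gene Os07g0129200 fell from 77.0 ± 21.5 to 20.7 ± 2.08 CPM (log2 −1.90 ± 0.20, adjusted p = 4.54e-05), while a listed chitinase, Os06g0726200, rose 3.09-fold (log2 1.63 ± 0.18, adjusted p = 2.72e-05), so that of 10 pathogenesis-related genes 2 rose and 2 fell, or 2 and 3 adjusted over the list alone. Without control replicate 1 the numbers were 3 and 1, or 3 and 3 adjusted over the list alone. The salicylate list had 1 of 5 genes lower, the WRKY45 factor Os05g0322900 (log2 −1.01, adjusted p = 0.0033), and 2 lower adjusted over the list alone (1 without control replicate 1). Of 7 genes of diterpenoid phytoalexins, the antimicrobial compounds of rice, 4 fell, and 5 adjusted over the list alone; Os04g0179200, listed as a momilactone synthase, went from 23.6 ± 8.47 to 7.18 ± 2.15 CPM (log2 −1.71 ± 0.35, adjusted p = 0.00934), and the listed cytochrome P450 Os04g0178400 had a log2 change of −0.77 (adjusted p = 0.00845). Camera called the diterpenoid list lower (median log2 −0.94, adjusted p = 0.00438; adjusted p = 0.222 with an estimated correlation) and the phenylpropanoid list lower (median −0.30, adjusted p = 0.0372; adjusted p = 0.261 with an estimated correlation). The phenylpropanoid call was lost without control replicate 1 (adjusted p = 0.141) or gall replicate 2 (0.094) and under a stricter count filter (0.357). In that list 1 of 7 genes fell, Os02g0626600 (log2 −0.98, adjusted p = 0.0123), whose call was lost without gall replicate 2 (0.059), and 4 adjusted over the list alone (1 without control replicate 1). Control replicate 1 had more of the PR1 gene Os07g0129200, 102 CPM against 64.4 and 64.9 in the other control libraries.

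Jasmonate genes showed no common direction between gall and root without AO. In the biosynthesis list 1 of 13 rose and 2 fell, the same numbers adjusted over the list alone. Without control replicate 1, 1 rose and 1 fell either way. The lipoxygenase Os05g0304600 was among those that fell with all libraries (log2 −0.77, adjusted p = 0.000491). In the signalling list 2 of 16 rose by edgeR, 2 rose and 4 fell by DESeq2, and 3 rose and 5 fell adjusted over the list alone. Without control replicate 1, where this list was higher, 2 rose and 0 fell adjusted over the list alone. The JAZ repressor Os03g0180800 had 55.0 CPM in that library, 10.5 and 3.1 in the other control libraries and a mean of 2.34 in galls (adjusted p = 0.0659, edgeR). On the rising side, the JAZ repressor Os07g0615200 had a log2 change of 0.47 (adjusted p = 0.0159), a call lost without control replicate 2 (0.0673) or gall replicates 1 (0.0701) or 3 (0.0813) and with only these 2 groups in the fit (0.0538). In the ascorbate list 2 of 26 rose and 2 fell, or 4 and 3 adjusted over the list alone; the peroxidase gene Os07g0694700 had a log2 change of −0.45 (adjusted p = 0.00551). Of the 2 listed ethylene-responsive factors 0 passed either way or had an unadjusted p under 0.05.

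The count for galls without AO was 2341 genes, 967 higher and 1374 lower. At 2-fold or more the excess of lower genes was gone, with 487 higher and 466 lower among 953. Groups did not overlap for 5493 genes, 28.2% of those tested, where chance gives 10%. A pair of unlisted genes had 0 counts in the control roots. With the control group set to a floor of 3 counts over the group, the gall mean was 69.9 times that floor for Os04g0516200 and 24.3 times for Os10g0430200. Only the control side is bounded in this way. The galls varied, with 6.23 ± 3.65 and 2.17 ± 1.11 CPM, so these are not lower limits of the rise. Os10g0335000, also unlisted, went from 31.4 ± 5.46 to 0.434 ± 0.448 CPM (adjusted p = 3.15e-05). The count was 1515 without gall replicate 1 and 1412 without gall replicate 3, 1525 under a stricter count filter and 1388 with only these 2 groups in the fit. Camera called 3 of 9 lists, and 0 with an estimated correlation.

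**Figure D3:**
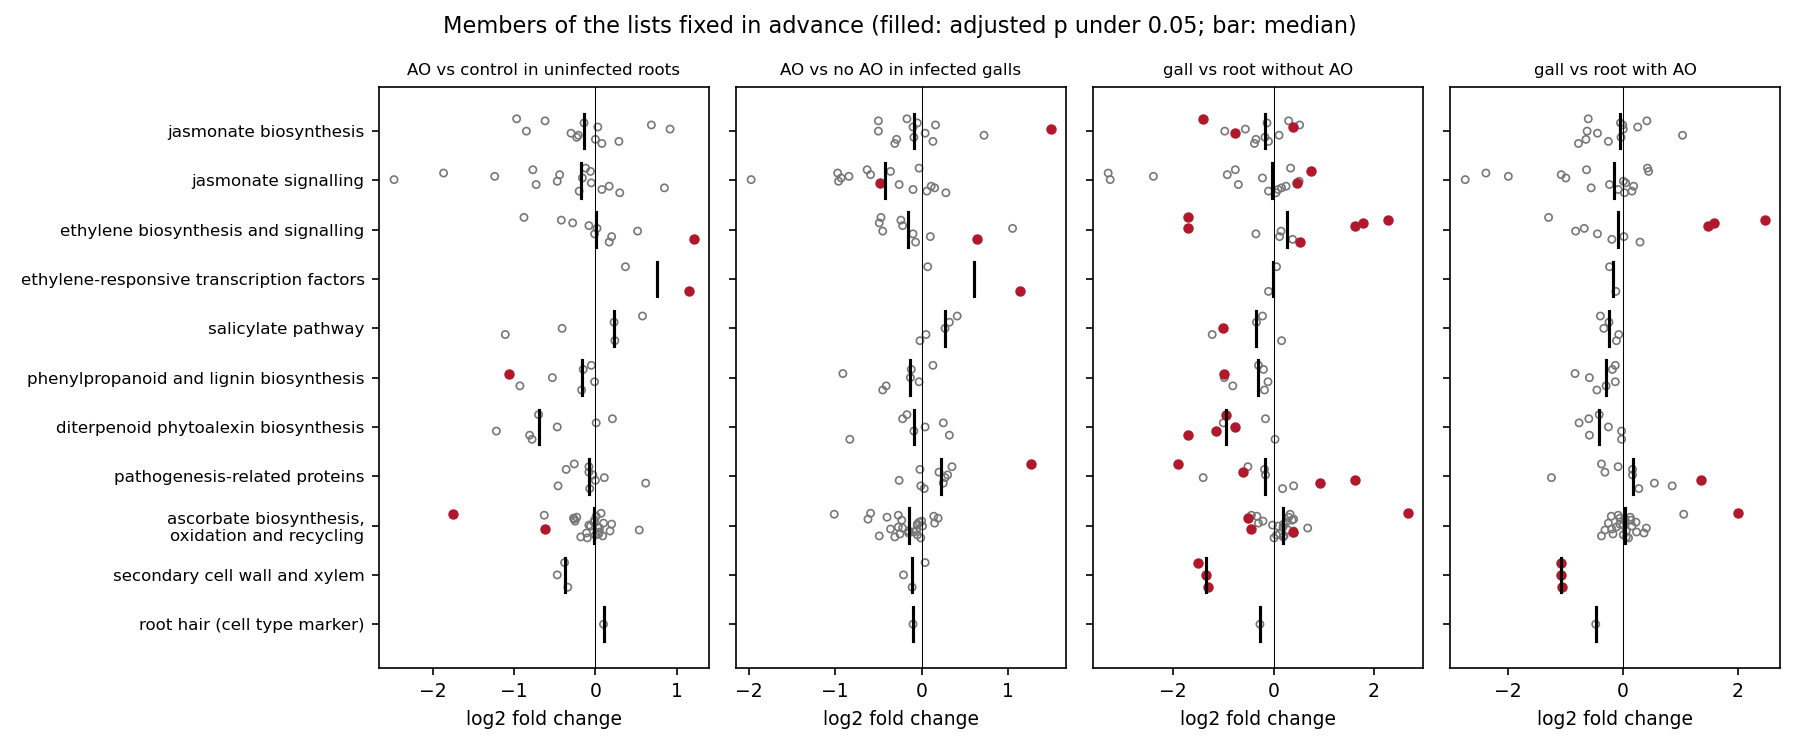
Log2 fold change of each tested member (points) of the 11 gene lists written in advance, in 4 comparisons; filled points have an adjusted p under 0.05 and bars are medians. All 3 secondary wall genes are filled and lie left of 0 in both comparisons of gall with root.

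With AO, galls again differed from AO-treated roots in ethylene and cell wall genes. The ACC oxidases Os09g0451400 (5.53-fold, log2 2.47 ± 0.28, adjusted p = 0.00014, edgeR, n = 3 per group) and Os02g0771600 (2.81-fold, log2 1.49 ± 0.23, adjusted p = 0.00246) rose. So did the ACC oxidase Os09g0451000 (2.99-fold, adjusted p = 0.029), whose call was lost without AO replicates 1 (0.0603), 2 (0.13) or 3 (0.113) or AO-treated gall replicates 1 (0.109) or 2 (0.0974), and without a count filter (0.0923). The chitinase Os06g0726200 rose 2.57-fold (log2 1.36 ± 0.18, adjusted p = 0.000462). The 3 cellulose synthases fell: Os01g0750300 from 105 ± 7.75 to 49.4 ± 13.2 CPM (log2 −1.08 ± 0.17, adjusted p = 0.00176), with log2 changes of −1.08 for Os10g0467800 (adjusted p = 0.00246) and −1.06 for Os09g0422500 (adjusted p = 0.00242). The secondary wall list was called lower by camera, the only 1 of 9 (adjusted p = 1.38e-09; adjusted p = 0.0433 with an estimated correlation). The number of lists called was 2 without AO replicate 1 or AO-treated gall replicate 3 and 3 without AO-treated gall replicate 1, all lower.

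Elsewhere few listed genes passed between gall and root with AO. In the ethylene list 3 of 10 rose, and 3 rose and 1 fell adjusted over the list alone. In the pathogenesis-related list 1 of 10 rose, and 3 rose and 1 fell adjusted over the list alone; the PR1 gene Os07g0129200 had a log2 difference of −0.37 ± 0.19 (adjusted p = 0.356). In the ascorbate list 1 of 26 rose, and 1 adjusted over the list alone. That gene was the ascorbate oxidase Os06g0567900 (log2 2.01, adjusted p = 0.0361), and leaving out any 1 of the 6 libraries ended its call, with an adjusted p of 0.127, 0.125 and 0.0924 without AO replicates 1, 2 and 3 and of 0.115, 0.0895 and 0.076 without AO-treated gall replicates 1, 2 and 3. In the jasmonate lists edgeR called 0 of 13 and 0 of 16 and DESeq2 1 and 0, with 4 and 6 at an unadjusted p under 0.05; adjusted over the list alone 1 biosynthesis gene was lower, and 1 signalling gene was higher and 1 lower. The salicylate, phenylpropanoid and diterpenoid lists and the 2 ethylene-responsive factors had 0 called members either way or by DESeq2, and 0, 1, 1 and 0 members with an unadjusted p under 0.05.

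The total was 772 genes, 402 higher and 370 lower, with 327 changed at least 2-fold, 208 higher and 119 lower. Which direction held more genes depended on the setting. The lower genes were the majority with only these 2 groups in the fit (589 higher, 933 lower), without control replicate 1 (786 and 941), by DESeq2 (428 and 552), under a stricter count filter (272 and 379), without AO-treated gall replicate 1 (241 and 269), with relative log expression size factors (374 and 395) and with the authors' size factors (373 and 392). Groups did not overlap for 4981 genes, 25.6% of those tested, where chance gives 10%. The unlisted gene Os06g0168700 went from 0.335 ± 0.158 to 30.6 ± 14 CPM (adjusted p = 9.49e-05) and Os10g0335000 from 37.0 ± 10.3 to 1.45 ± 0.964 CPM (adjusted p = 0.000267). Without AO replicates 1, 2 and 3 the count was 410, 348 and 423, and without AO-treated gall replicates 1 and 2 it was 510 and 405. It was 1522 with only these 2 groups in the fit and 1727 without control replicate 1, which is in neither group.

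The gall responses without and with AO overlapped in 298 higher and 254 lower genes, where 20.0 and 26.1 were expected if the calls were independent (two-sided Fisher's exact test, p = 1e-300 or less and 9.83e-208). The 3 cellulose synthases, the 3 rising ACC oxidases and the chitinase Os06g0726200 were among them. By edgeR 0 genes were called in opposite directions, and 97.8% of the 402 genes higher with AO had a positive difference without AO. Across genes, which are not independent replicates, Pearson's r was 0.66 and Spearman's rho 0.52. The overlap of 552 genes fell to 324, 282 and 340 without AO replicates 1, 2 and 3 and to 318 without AO-treated gall replicate 2, and was 1006 without control replicate 1.

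**Figure D4:**
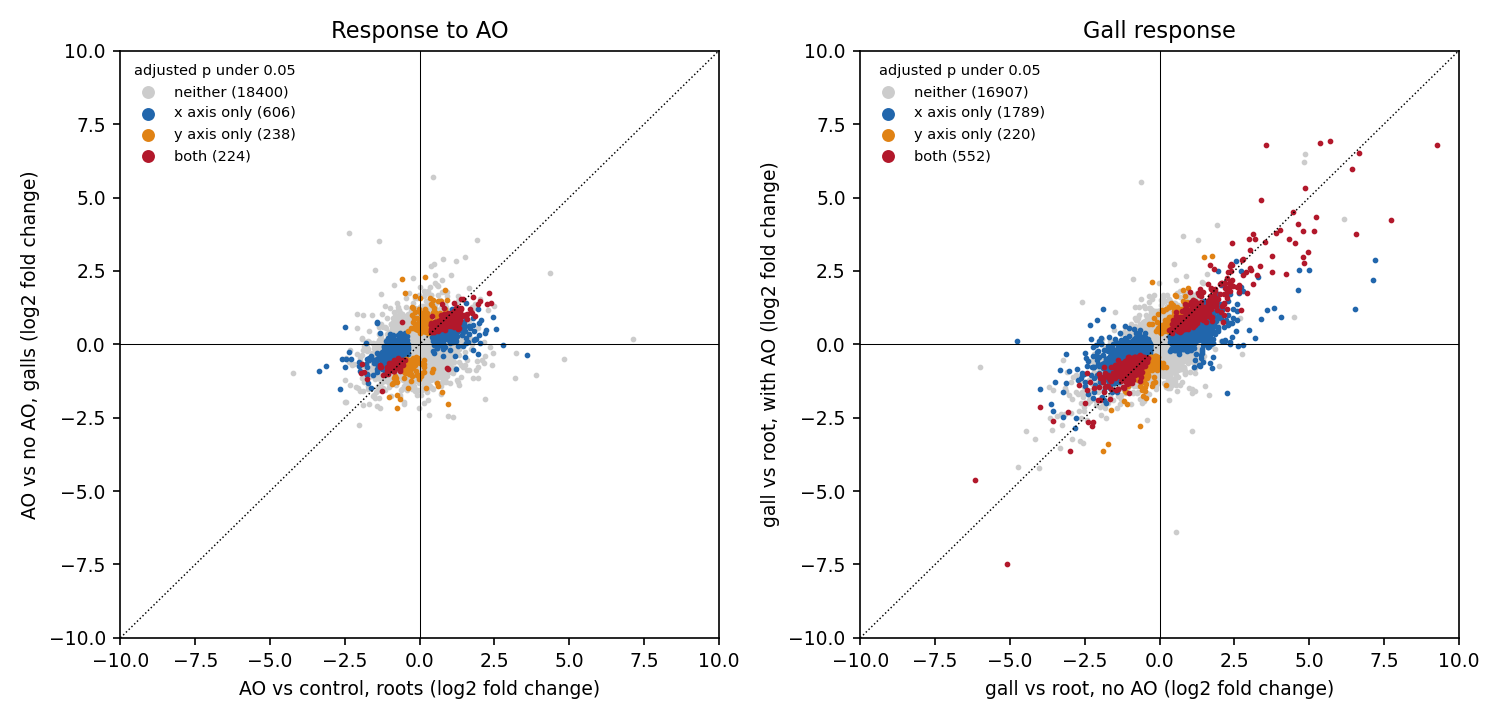
Each point is 1 of 19468 genes. Left, the log2 fold change for AO in roots (x axis) against galls (y axis); right, gall against root without AO (x axis) and with AO (y axis), with colours for genes with an adjusted p under 0.05 in both (224 left, 552 right), either or neither comparison and a dotted line of equal change.

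The interaction tested whether the response to AO differed between galls and roots, which equals asking whether the gall difference depended on AO. Of the genes in lists written in advance, 0 passed by edgeR and 1 by DESeq2. The PR1 gene Os07g0129200 came nearest, with AO changing it by 1.52 ± 0.28 log2 units more in galls than in roots (adjusted p = 0.11 by edgeR and 0.000565 by DESeq2); it was the only member of its list of 10 that passed adjusted over the list alone. The WRKY45 factor Os05g0322900 (0.69 ± 0.27, adjusted p = 0.567), the ethylene receptor Os04g0169100 (−0.58 ± 0.22, adjusted p = 0.539) and the cellulose synthase Os01g0750300 (0.42 ± 0.23, adjusted p = 0.723) did not pass, so a difference between the tissues in their response to AO is not shown. In the other 8 tested lists 0 members passed, over all genes by either tool or adjusted over the list alone, and 0 to 2 members of each had an unadjusted p under 0.05. Camera called 0 of 9 lists; the pathogenesis-related list was nearest (median 0.31, 8 of 10 positive, adjusted p = 0.0932).

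In all, 7 genes passed the interaction test, 3 higher and 4 lower, 1496 had an unadjusted p under 0.05, and DESeq2 called 60, 41 higher and 19 lower. The higher genes were also the majority with a replicate block (4 and 3) and without a count filter (14 and 8). Os05g0460000 averaged 49.4 ± 5.17 CPM in control roots, 12.9 ± 1.84 in AO-treated roots, 23.0 ± 1.91 in galls and 14.3 ± 0.623 in AO-treated galls (interaction log2 1.25 ± 0.19, adjusted p = 0.0361). Os10g0165300 averaged 1.36, 2.09, 6.26 and 2.33 CPM in the same order (interaction log2 −2.05 ± 0.34, adjusted p = 0.0477, and 0.0676 with a replicate block). The count rested on single libraries. It was 33 without control replicate 1 (26 higher, 7 lower), 3 without AO-treated gall replicate 2, and 1 without control replicate 3 or gall replicate 1. It was 0 without control replicate 2, gall replicates 2 or 3, any AO replicate or AO-treated gall replicate 3, and 0 under a stricter count filter. Lists called were 2 without AO-treated gall replicate 2, and 1 without control replicates 1 or 2, gall replicates 1 or 3, or AO replicate 2.

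Loci of 4 insertion mutants named in the study's labels were followed in each comparison. JAR1 Os05g0586200, which joins jasmonate to isoleucine, had log2 differences of 0.08 with AO in roots and −0.31 with AO in galls. GME Os10g0417600 and PMI Os01g0127900, both of ascorbate synthesis, stood at 0.01 and 0.10 with AO in roots. None of the 3 passed in any of the 5 comparisons. Between gall and root with AO, JAR1 (log2 −0.77, adjusted p = 0.134) passed when AO replicate 3 was left out (log2 −1.04, adjusted p = 0.0242). Between gall and root without AO, GME passed without control replicate 3 (log2 −0.38, adjusted p = 0.0466) and by DESeq2 (adjusted p = 0.0489). APX8 Os02g0553200 averaged 3.67 counts per library and was not tested, so a difference in it was not detectable at this depth. The single tested root hair gene, Os06g0184000, did not pass in any comparison, over all genes or adjusted over the list alone; alone in its list, it passed as lower between gall and root without AO when control replicate 1 was left out.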

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

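Of the tests below, the comparison of library totals for control replicate 1, the slope that takes each group's own spread, the standard errors over fits that leave out 1 library, the make-up of the splits for the interaction, and all tests of the iron, nitrate and aquaporin lists were chosen only after the result was seen.

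The interaction test, which asks whether the effect of AO differs between galls and roots, called 7 genes. Those with the largest changes were Os07g0525100 (log2 1.37), Os05g0460000 (1.25), Os10g0165300 (−2.05) and Os05g0525900 (−2.01). Each was called with all 12 libraries, and each lost its call in most fits that left out 1 library: the adjusted p then reached 0.155 for Os07g0525100 without AO replicate 3, 0.155 for Os05g0460000 without AO replicate 3, 0.156 for Os10g0165300 without AO replicate 2 and 0.155 for Os05g0525900 without AO replicate 3. Of 100 ways to split the 12 libraries, the real one included, 5 called as many genes and the highest of the others called 78, so chance is not excluded for this count. Nor can this test decide on chance, because a free split can set mostly galls against mostly roots. A count of 78, several times the real one, points to a structure among the libraries. The split that gave it set 4 galls and 1 library with AO against 2 galls and 5 libraries with AO, and the other 3 that called as many as the real one, with 71, 69 and 10 genes, set 5 galls against 1. The 44 drawn splits with 3 galls on each side called 0 genes. Such splits can mix galls and roots within a fitted group, where the difference between them counts as spread and lowers the calls. Those counts of 0 thus say nothing about the real grouping, and whether the groups themselves are that structure is not decided.

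As lists, the aquaporins (adjusted p = 1.25e-06), the iron acquisition genes (1.34e-06) and the nitrate, ammonium and phosphate transporters (0.000738) were called higher in the interaction by camera. With an estimated correlation the adjusted p was 0.0972, 0.178 and 0.178, and by edgeR 0 members of any of the 3 lists passed singly over all genes. Adjusted over the list alone 6, 2 and 1 members passed, all higher. An unadjusted p under 0.05 was reached by 6, 6 and 2 members, and DESeq2 called 3, 0 and 1.

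Fewer genes were called between gall and root with AO (772) than without (2341), a ratio of 3.03 that came down to 1.53 without control replicate 1 and ran up to 6.35 over the 12 fits that leave out 1 library. For lower precision as the whole cause, the rule set in advance spoke against it. The slope of the changes with AO on those without, corrected for noise, was at most 0.73 where equal changes give 1. Its lowest value was 0.58 and its standard error 0.12. That slope assumes a spread shared by all groups, though control replicate 1 stood apart. With each group's own spread the slope was 0.755 and ran from 0.66 to 0.96, the highest without control replicate 2. As that range comes close to 1, lower precision stays open. With only the compared groups in the fit the counts turned round, 1388 without AO and 1522 with it, so the counts alone do not rank the comparisons. Control replicate 1 stays open as a cause, since 1.53 differs from the bound of 1.5 set in advance by less than the spread of the ratio (SD 1.57). A smaller share of gall tissue in AO-treated galls cannot be told apart from a weaker response. The share kept was the difference of AO-treated galls from AO-treated roots, over the difference of untreated galls from AO-treated roots. Its median was 0.55 for genes higher in galls and 0.767 for genes lower. Simulated data with the full difference put in gave 0.89 and 0.96 for genes picked in the same way. The gap of 0.22 (0.16 to 0.32) passed the bound of 0.15 set in advance by less than its standard error of 0.15. Simulated mixes with 1 common share left gaps of up to 0.08. In the simulations AO-treated roots had the level of control roots. They thus left out the effect of AO in roots and are only a rough guide.

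Control replicate 1 differed from the other control libraries, with 1968 genes over 1 log2 unit away, 759 higher and 1209 lower. Lower depth is argued against, since its total was 1.00 times the median of the 12 libraries. Green tissue is argued against, since the summed CPM of that list was at least 1.07 times, and under 1.5 times, that of the other 2 libraries. A jasmonate-type response in that pool of plants may be part of the difference, but its median of 0.58 lies between the bounds set in advance, and with 1 library it cannot be decided. Nor was the difference particular to jasmonate genes. The WRKY list, written after the files were read, had a median 1.12 log2 units higher in that library, with 10 of 11 members higher. The pathogenesis-related and diterpenoid lists had medians of −0.07 and −0.01. The labels give nothing that sets this library apart, so no other biological explanation was tested.

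By camera the iron acquisition list was lower in AO-treated roots (median log2 −0.39, 11 of 12 members negative, 2 of 12 passing singly) and higher in the interaction (median 0.56, 11 of 12 positive). In the interaction 0 members passed over all genes by edgeR or DESeq2, 2 passed adjusted over the list alone and 6 had an unadjusted p under 0.05. Both camera calls of the list were lost with an estimated correlation (adjusted p = 0.422 in roots and adjusted p = 0.178 in the interaction). Control replicate 1 is argued against as the cause, since the interaction median was 0.50 without it. Library scaling stays open: the median was at least 0.54 with other size factors, but these moved the median of all genes by at most 0.016 and so could not have changed that of the list much. An effect of AO on iron uptake that depends on tissue was not tested apart from these and may be no more than a hypothesis.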

How the results depend on the processing

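Leaving out control replicate 1 for the comparisons that do not contain it, or for counts adjusted over a list alone, was chosen only after that library was seen to stand apart, and so were the tests of the added lists and their members. Of 65 results for named genes past the threshold, 38 kept their direction and side of the threshold in every alternative run for them; of their 856 alternatives 713 were the same, 143 lost the call and 0 reversed. Of 7 calls of lists written in advance 1 held in every alternative, with 75 of 95 alternatives the same, 20 weaker and 0 reversed; of 13 calls of added lists 1 held, with 164 of 187 the same, 23 weaker and 0 reversed. Of 62 called members of the added lists 34 held, with 718 of 821 the same, 103 weaker and 0 reversed. No scaling moved the median of all genes by over 0.1. Where a cause is not given below, the cause was not tested.

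The libraries' numbers do not pair them: 4 of 18 correlations between libraries of the same number exceeded 0.1 (−0.111 to 0.329), and in 14 of 36 comparisons a library matched its own number best. The replicate block gave 915, 495, 2486 and 836 genes for AO in roots, AO in galls, gall without AO and gall with AO, 7 for the interaction, and 1 list in the interaction where the fit without a block called 0.

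A required log2 change of 1 lowers counts by its construction, to 241, 93, 953 and 327 genes in the same order. With only the compared groups in the fit the counts were 356, 900, 1388 and 1522, and lists called were 1 for AO in roots and 3 for gall with AO. The stricter count filter, which tests fewer genes, called 1525 genes for gall without AO, 0 for the interaction, 1 list for AO in galls and 2 lists for gall with AO. It called 41.8% of genes higher for gall with AO, against 52.1% in the report, and the size factors of DESeq2's kind or the authors' own also left the higher genes in the minority there (374 of 769 and 373 of 765). No count filter called 22 genes for the interaction and 2 lists for AO in roots. DESeq2 called 60 genes for the interaction. With an estimated correlation 0 lists were called for AO in galls and for gall without AO.

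Over fits that leave out 1 library the counts ran from 399 to 1021 for AO in roots, 176 to 406 for AO in galls (1124 without control replicate 1), 1412 to 2686 for gall without AO, 348 to 522 for gall with AO (1727 without control replicate 1) and 0 to 33 for the interaction. Lists called ran from 0 to 2, 1 to 4, 2 to 4, 1 to 3 and 0 to 2 in the same order. The overlaps ran from 112 to 413 for AO and from 282 to 1006 for galls, both highest without control replicate 1. Fewer libraries cannot account for the rises among these. The common biological coefficient of variation, the spread between libraries that all comparisons share, was 0.159 with all 12 libraries. It was 0.116 without control replicate 1, 0.144 without control replicate 3 and 0.16 to 0.167 without any 1 of the others. A smaller shared spread lets more genes pass, but its part in the rises was not tested apart.

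Only uncalled loci of the insertion mutants changed sign. With AO in roots, log2 differences ran from −0.25 to 0.35 for Os05g0586200, −0.06 to 0.14 for Os10g0417600 and −0.02 to 0.30 for Os01g0127900. For Os01g0127900 they ran from −0.11 to 0.44 with AO in galls, −0.51 to 0.04 for gall with AO and −0.21 to 0.34 for the interaction. Os01g0127900 averaged 1.35 CPM in control roots, where a small difference is not detectable at this depth.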

Other observations

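The members of the lists in this part, and so the tests on them, were chosen only after the files had been read. The splits of libraries at the end were planned.

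Aquaporins, which let water through membranes, were lower as a list in galls than in roots without AO: 8 of 13 fell, and all 13 had negative differences (median log2 −0.83, camera adjusted p = 1.68e-12; adjusted p = 0.0154 with an estimated correlation); Os02g0629200 (log2 −1.11, adjusted p = 2.42e-05) and Os04g0521100 (log2 −1.04, adjusted p = 1.11e-05) are examples. Of 12 iron acquisition genes 6 fell and 11 had negative differences (median −0.69, adjusted p = 1.24e-06; adjusted p = 0.165 with an estimated correlation), among them Os03g0307200 (log2 −0.95) and Os11g0134900 (log2 −0.86; its recalled symbol stands on another chromosome in the reference table). Of 14 genes of nitrate, ammonium and phosphate transport 6 fell and 12 had negative differences (median −0.47, adjusted p = 6.24e-05; adjusted p = 0.128 with an estimated correlation), led by Os01g0704100 (log2 −2.43, adjusted p = 5.84e-05). Of 11 WRKY transcription factors 3 fell (median −1.01, adjusted p = 6.24e-05; adjusted p = 0.199 with an estimated correlation), and this list stood 1.12 log2 units higher at its median in control replicate 1 than in the other control libraries. Class III peroxidases, which act on cell walls and hydrogen peroxide, went both ways, with 3 of 12 higher and 3 lower: Os07g0677200 rose (log2 1.45, adjusted p = 0.000133) and Os05g0135500 fell (log2 −2.06, adjusted p = 1.05e-05). Of 14 sugar transport and cleavage genes 2 rose and 3 fell, with Os02g0106100, whose recalled symbol also stands on another chromosome, at log2 −1.79 (adjusted p = 0.000347). Of 12 cell cycle genes and 5 green tissue genes 0 passed by edgeR, over all genes or the list alone, and 0 by DESeq2; 2 and 1 had an unadjusted p under 0.05.

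In AO-treated roots the transport list was lower (4 of 14 genes, median −0.28, adjusted p = 4.38e-05; adjusted p = 0.177 with an estimated correlation), with Os02g0112600 (log2 −1.33, adjusted p = 0.000416) as an example. The iron list was lower too (2 of 12 genes, median −0.39, adjusted p = 0.000546; adjusted p = 0.422 with an estimated correlation), as were the aquaporins (1 of 13, adjusted p = 0.0291; adjusted p = 0.422 with an estimated correlation), a call lost without control replicates 2 (0.152) or 3 (0.0581) or AO replicate 3 (0.0977), under a stricter count filter (0.0911) and with only these 2 groups in the fit (0.0591). In AO-treated against untreated galls the aquaporins were higher (3 of 13, median 0.12, adjusted p = 0.0245; adjusted p = 0.852 with an estimated correlation), among them Os04g0521100 (log2 0.57, adjusted p = 0.00602); the call for the list was lost without gall replicates 2 (0.0603) or 3 (0.0589) or AO-treated gall replicate 1 (0.285), and under a stricter count filter (0.0644). In the transport list Os02g0112600 fell in galls as well as in roots (log2 −0.78, adjusted p = 0.0225), 1 of 14 by edgeR and 2 by DESeq2. In the sugar list 2 of 14 rose there, Os11g0508600 (log2 0.87, adjusted p = 0.0142) and Os03g0170900 (log2 0.67, adjusted p = 0.0324). The call of Os02g0112600 was lost without gall replicates 2 (0.0836) or 3 (0.115) or AO-treated gall replicates 1 (0.0902), 2 (0.0672) or 3 (0.0932), and that of Os11g0508600 without gall replicates 1 (0.0701) or 2 (0.0647) or AO-treated gall replicate 3 (0.0816). That of Os03g0170900 was lost without gall replicates 1 (0.165) or 2 (0.137) or AO-treated gall replicates 1 (0.0748), 2 (0.102) or 3 (0.103). With AO, galls had 5 of 13 aquaporins lower and 1 higher than roots (adjusted p = 0.000222; adjusted p = 0.25 with an estimated correlation), and the WRKY list was lower with 0 of 11 members called by edgeR or DESeq2 and 6 at an unadjusted p under 0.05 (adjusted p = 0.000985; adjusted p = 0.556 with an estimated correlation), which was lost without AO replicate 2 (0.0513) and under a stricter count filter (0.098). The class III peroxidases again went both ways between gall and root with AO, with 3 of 12 higher, led by Os01g0327100 (log2 1.17, adjusted p = 0.00181), and 2 lower, led by Os05g0135500 (log2 −1.91, adjusted p = 9.3e-05). Among the other lists of this part, 1 iron gene rose there, Os07g0689600 (log2 0.57, adjusted p = 0.0211), a call lost without AO replicates 1 (0.0737) or 3 (0.109) or AO-treated gall replicates 2 (0.114) or 3 (0.0747), and 1 transport gene and 1 sugar gene fell.

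Other splits of the 6 libraries of each comparison of groups called hardly any genes. For AO in roots, 1 of 10 splits, the real one, called 830 genes and the highest other called 1. For AO in galls the real split called 462 and the highest other 1. For gall against root without and with AO the real splits called 2341 and 772 and the highest others 0. Every other split put libraries of both groups on each side. A real difference then counts as spread within a side and lowers the calls, so the low counts say nothing about chance. With 10 splits no share under 0.05 can be reached.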
